A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

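The series measured DNA copy number along the genome of budding yeast (Saccharomyces cerevisiae) in cells sorted for S phase, the part of the cell cycle in which the genome is copied. Per the labels' protocols, cells were taken from mid-log cultures in YPDA, a rich medium, and stained with the DNA dye Sytox Green so that single cells with S phase DNA content could be sorted. Per the labels' protocols, DNA was purified with phenol and chloroform, and libraries followed the NEB Ultra II instructions. Per the series design text, sequencing was on an Illumina NextSeq instrument. Both strains carry the W303 background and both are diploid by their mating type labels. There was 1 library of RWY012 and 1 library of RWY109.

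The submitters' processing notes name the sacCer3 genome build, Bowtie2 2.2.5, SAMtools 1.3.1 and bedtools 2.26.0, without settings. Per the series design text, the deposited values are counts of uniquely mapped reads in bins of 1 kb. The deposited counts are whole numbers with no normalization, and bins without a read are not listed, so an unlisted bin was taken as 0. Counting unique reads lowers the signal of sequences present in several copies, such as Ty elements, to an extent that differs between loci. Whether duplicate reads were removed was not given in the sources used here. Intervals below therefore cover counting error only.

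The RWY012 library held 54525773 counts, of which 49236979 lay on the 16 nuclear chromosomes. The RWY109 library held 15663187 counts, of which 14526167 were nuclear, so RWY012 was 3.39 times as deep. Bins were retained where they were nuclear, of full length and at 0.25 or more of the library median in both libraries. This kept 11312 bins and 99.8% of nuclear counts in each library. The median retained bin held 4100 counts in RWY012 and 1219 counts in RWY109, which gives a counting SD of 1.56% and 2.86% per bin.

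Each library was divided by its median retained bin. Gene coordinates and symbols came from the RefSeq gene table of the same assembly. That table gives no replication origins, so the planned comparison of single origins was replaced by windows around centromeres and at chromosome ends. Origins named in advance were not analysed here. Centromeres were placed midway between the innermost left-arm and right-arm open reading frames.

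A locus level was the summed count over bins lying at least 50% inside the gene, or over the bin holding most of it. Levels had exact Poisson intervals and ratios had exact conditional Clopper-Pearson intervals, all at 95%. A chromosome was called different where its median log2 ratio lay at least 0.2 from the median of the 16 chromosomes. That median was -0.067, since gained DNA in 1 library shifts its scaling, and chromosome and gene list ratios are given relative to it. The spread along a chromosome was the SD of medians over 50 kb windows. Segments came from optimal partitioning with a minimum of 10 bins and a penalty factor of 5. A segment was called where it differed by at least 0.3 log2 from the rest of its chromosome, and neighbouring pieces past this rule were joined.

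Replication profiles were log2 levels relative to the median of the chromosome or segment, smoothed with a running median and then a running mean of 5 bins. Centromere windows reached 25 kb to either side and end windows covered 30 kb. Each window list was placed among 10000 random lists of equal size matched on level. Counting intervals of profile values came from 200 Poisson resamples. The genes to be named were the loci in the genotypes, chromosomes and segments past these rules, members of 7 fixed gene lists in gained regions, and single bins past 4-fold with at least 50 counts. These rules, the gene lists and most alternatives were fixed before the data were examined.

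With 1 library per strain, no test across samples was possible and no replicate error could be given. Alternatives covered library scaling, bin filters, thinning of RWY012 to the nuclear total of RWY109, odd and even bins, summed counts, segmentation settings, window widths, smoothing and the local reference of each locus. The planned correction for GC content was not run because no genome sequence was used here. The methods were tested on simulated counts built from the RWY012 library, with only the depth taken from RWY109. A planted 1.5-fold chromosome gain came back at log2 0.59, and a planted 100 kb duplication at log2 0.99 with an edge error of 0 kb. That duplication ended on bin borders, so its edge error does not bear on ends that lie in stretches without retained bins. Profiles widened 1.1 times gave an SD ratio of 1.10, and unchanged profiles gave 0 called chromosomes and 0 called segments. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.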

Results

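DNA copy number was measured by sort-seq in S phase cells of 2 diploid yeast strains of the W303 background. In sort-seq, DNA from S phase cells is sequenced and counted along the chromosomes, so that sequences copied early in S phase give more reads than sequences copied late. RWY012 carries rad53::LEU2 and sml1::URA3 on both homologues. RAD53 encodes the checkpoint kinase that responds to replication stress, and SML1 encodes an inhibitor of ribonucleotide reductase. RWY109 carries a deletion of DBF4 with dbf4-4A placed at HIS3, sld3-38A and a deletion within MCM4, together with a deletion of SML1. Dbf4, Sld3 and Mcm4 act in the firing of replication origins. Each strain had 1 library and no replicates, so the values below compare these libraries and carry counting error only. The RWY012 library held 54525773 counts and the RWY109 library 15663187 counts, in 1 kb bins of the sacCer3 build.

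The genes named in the genotypes were examined first, to check the strain labels. RAD53 DNA was nearly absent from RWY012 and at the genome level in RWY109. RAD53 lies on chromosome XVI from 261727 to 264192, and the 2 bins wholly inside it held 4 counts in RWY012 against 2650 counts in RWY109. After scaling, RWY012 stood at 0.0449% of the RWY109 level (95% counting interval 0.0122 to 0.115%). No other bins outside called regions passed a 4-fold difference with at least 50 counts, so these 2 bins were the complete set. LEU2, the leucine marker at the RAD53 locus, was higher in RWY012, at 2.01 times the library median against 1.13 in RWY109. The ratio of RWY109 to RWY012 at LEU2 was 0.565 (0.533 to 0.598).

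The markers of RWY109 showed the opposite direction. TRP1, a tryptophan synthesis gene used to replace DBF4, stood at 2.25 times the library median in RWY109 and 1.32 in RWY012, a ratio of 1.70 (1.62 to 1.78). HIS3, the histidine gene at the site of the dbf4-4A construct, stood at 1.36 and 0.716, a ratio of 1.91 (1.79 to 2.02). URA3, the marker at SML1 in both strains, was raised in both, at 1.90 in RWY012 and 2.18 in RWY109. The bin holding most of SML1 was at 0.651 in RWY012 and 0.759 in RWY109. That bin holds only 315 bp of SML1, so its level mixes the gene with its surroundings.

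The altered initiation genes of RWY109 each had a local dip. At DBF4, the activator of the Cdc7 kinase, the ratio of RWY109 to RWY012 was 0.830 (0.795 to 0.866), or 0.748 (0.717 to 0.781) against the bins 5 to 25 kb away. In the 1 bin wholly inside DBF4 it was 0.651 (0.608 to 0.696). At SLD3 the bin from 297001 to 298000 on chromosome VII fell to a ratio of 0.623 (0.579 to 0.669) against the same kind of surroundings, while the bin to its left was at 0.973. MCM4 encodes a subunit of the replicative helicase, and its label gives residues 74 to 174 as deleted, which correspond to chromosome XVI from 596969 to 597271. The bin from 597001 to 598000 held 3419 counts in RWY012 and 704 counts in RWY109. Relative to its surroundings this bin had lost 32.2% of its level in RWY109 (26.4 to 37.5%), and the deleted residues cover 27.1% of it. ADE2 differed by less than its counting error, with a ratio of 1.03 (0.979 to 1.07). Among the mating type loci, the bin of HMRA1 gave a ratio of 0.984 (0.917 to 1.05). The bins of MATALPHA1 and MATALPHA2 held 0 counts and 1 count in each library, and that of HMLALPHA1 held 97 counts in RWY012 and 27 counts in RWY109, too few unique reads to compare.

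**Figure D1:**
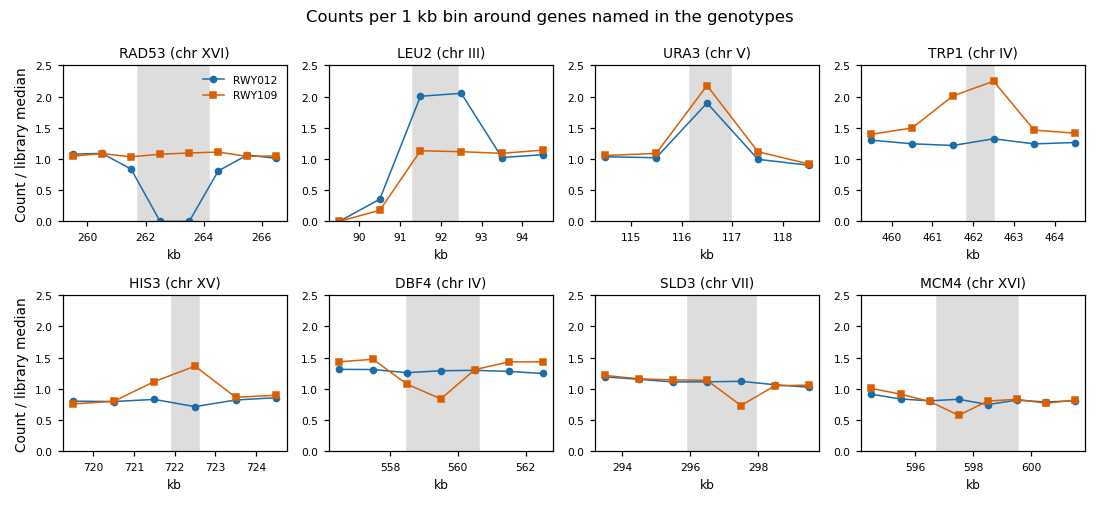
Counts per 1 kb bin divided by the library median (vertical axis) against position in kb for 8 genes named in the genotypes, with the gene shaded, RWY012 as circles and RWY109 as squares. RAD53 falls to 4 counts over 2 bins in RWY012, LEU2 is higher in RWY012, TRP1 and HIS3 are higher in RWY109, and DBF4, SLD3 and MCM4 dip in RWY109.

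Whole-chromosome copy number was compared next, since the series design names aneuploidy of chromosomes XI and XII in RWY012. Both chromosomes were higher in RWY012 than in RWY109 along their whole length. Chromosome XI was 1.48-fold higher (log2 0.57, SD 0.047 over 14 windows of 50 kb) and chromosome XII was 1.50-fold higher (log2 0.58, SD 0.048 over 22 windows). The ratio of 3 copies to 2 copies is 1.5. In RWY012 these chromosomes stood at 1.46 and 1.41 times the library median, and in RWY109 at 1.05 and 0.987, which assigns the difference to RWY012. The lowest window on chromosome XI was at log2 0.52 and the lowest on chromosome XII at log2 0.48, so no 50 kb window of either returned to the level of the other chromosomes. The other 14 chromosomes ranged from log2 -0.068 on chromosome I to 0.019 on chromosome VII. Summed counts in place of medians gave log2 0.48 for chromosome XII, as that sum includes the bins of the ribosomal DNA.

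**Figure D2:**
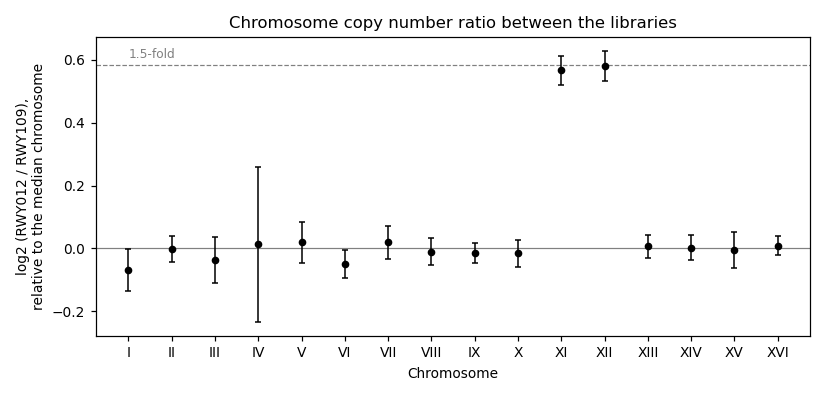
Median log2 ratio of RWY012 to RWY109 for each of the 16 nuclear chromosomes, relative to the median chromosome, with bars showing the SD of 50 kb window medians and a dashed line at 1.5-fold. Chromosomes XI and XII lie at 0.57 and 0.58, the others between -0.068 and 0.019, and the wide bar on chromosome IV comes from its duplicated segment.

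The gained chromosomes hold 318 and 520 coding genes, among them 13 of the 119 members of the gene lists fixed in advance. The lists were not compared with all coding genes, so the counts below give locations and no excess of any list. Of 30 replication initiation genes, 4 were gained in RWY012. ORC3, a subunit of the origin recognition complex, was at 1.61-fold (1.55 to 1.67), and MCM5, a helicase subunit, at 1.56-fold (1.49 to 1.64). CDC45, which joins the helicase at firing, was at 1.52-fold (1.46 to 1.59), and SLD2, a substrate of the S phase cyclin kinase, at 1.50-fold (1.44 to 1.57). Of 27 fork and polymerase genes, 2 were gained, the primase subunit gene PRI2 at 1.43-fold and the flap nuclease gene RAD27 at 1.44-fold. Of 18 checkpoint genes, MEC3 and SLX4 were gained, at 1.59-fold and 1.49-fold. Of 13 dNTP supply genes, 2 were gained, and both act on ribonucleotide reductase: RFX1, a repressor of its genes, at 1.50-fold and DIF1, a regulator of its subunit localisation, at 1.32-fold (1.25 to 1.40). Of 13 origin timing genes, the silencing genes SIR1 and SIR3 were gained, at 1.40-fold each, and of 8 dosage-sensitive genes SPC42, a spindle pole body gene, at 1.55-fold. None of the 10 histone genes lay on a gained chromosome. Outside gained regions and apart from the genotype loci, 97 list members ranged from 0.883-fold (CLB6) to 1.13-fold (HHF2) in RWY109 over RWY012, with a median of 1.00-fold. These are DNA levels and not expression.

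Segmental copy number was compared because the series design names a duplicated region of chromosome IV in RWY109. A single segment was called, joined from 2 neighbouring pieces that each passed the rule, and it was higher in RWY109. It ran from 884001 to 981000 on chromosome IV, 97 kb in length, at log2 1.02 (1.01 to 1.02), or 2.02-fold over the rest of the chromosome. In the 11 windows of 10 kb the fold ranged from 1.83 to 2.24. RWY109 stood at 2.21 times and RWY012 at 1.08 times its own level over the rest of chromosome IV, which places the change in RWY109. The ratio of 4 copies to 2 copies is 2.

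The segment holds 50 genes, of which 48 code for proteins. From the fixed lists it holds RAD9, a DNA damage checkpoint adaptor, at 2.13-fold (2.08 to 2.18), the histone genes HTA1 and HTB1 at 2.12-fold (2.02 to 2.22) and 2.01-fold (1.92 to 2.10), and SIR4, a silencing gene, at 2.11-fold (2.07 to 2.16). Other genes inside include GCD6, TCP1, UPC2, ADR1, PCF11, HEM1, SEC26, PRP28 and HSP78, named after the segment was seen. Each end met a stretch of 12 kb without retained bins, in which unique reads were few in both libraries. The left stretch holds YDR210W-B from 872112 to 877425 and YDR210C-D from 878659 to 883927, and the right stretch holds YDR261W-B from 981462 to 986775 and YDR261C-D from 987534 to 992349. All 4 are open reading frames of Ty retrotransposons, which are present in many copies. They are those of the reference assembly, and whether these W303 strains carry them at these sites was not tested. The bin from 871001 to 872000 was at 0.945 times and the bin from 993001 to 994000 at 0.999 times the ratio of the rest of the chromosome, so the retained bins place the ends within these stretches. A few bins below the filter lie inside the stretches. The bin from 877001 to 878000, with 421 counts in RWY012 and 111 counts in RWY109, was at 0.858. The bin from 878001 to 879000, with 1138 counts in RWY012 and 299 counts in RWY109, was at 0.855. Both lie below the segment's level, which places the left end between 879000 and 884001. On the right, the bin from 981001 to 982000 was at 2.08, that from 987001 to 988000 at 1.48 and that from 992001 to 993000 at 0.977. The first and last of these place the right end between 982000 and 992001. The middle bin, with 369 counts in RWY012 and 168 counts in RWY109, lay between the 2 levels and was not used to narrow these limits. Segmentation without the filter on low bins placed the ends at 872001 and 988000. The bin at that left edge held 1 count in each library, so that position carries no weight. The exact position of each end within these limits is left open.

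**Figure D3:**
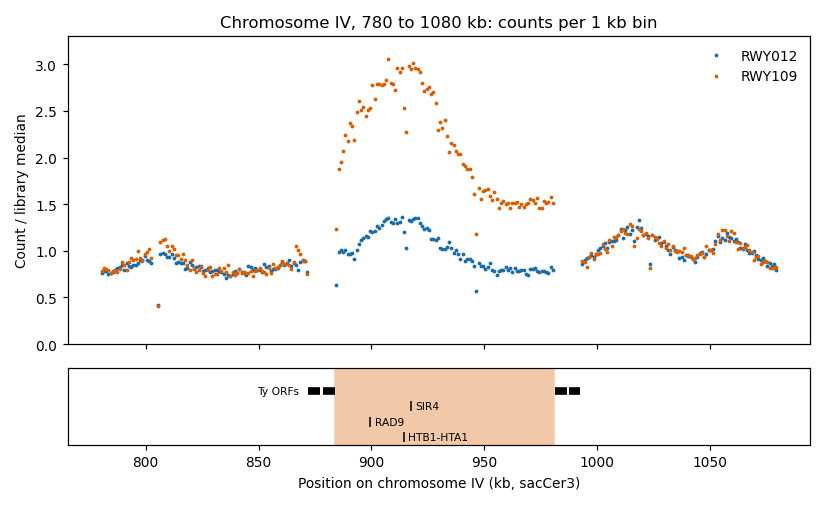
Counts per 1 kb bin divided by the library median against position on chromosome IV in kb, with the called segment, the Ty open reading frames longer than 4 kb and 4 list genes drawn below. RWY109 lies above RWY012 between 884001 and 981000, by 2.02-fold relative to the rest of the chromosome, and both libraries lack retained bins over the Ty reading frames.

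The profile of S phase copy number along each chromosome was compared last, since it reports on when each region is copied. Both libraries had the same main pattern of peaks and valleys, and its range was slightly wider in RWY109. The SD of the smoothed log2 level was 0.227 in RWY012 and 0.252 in RWY109, a difference of 0.0249 (0.0241 to 0.0262). From the 5th to the 95th percentile the level spanned 1.64-fold in RWY012 and 1.73-fold in RWY109. The profiles correlated across the 11312 bins at r = 0.966, and bins are not independent replicates. By chromosome r ranged from 0.939 on chromosome V to 0.979 on chromosome II, and the SD was larger in RWY109 on 16 of 16 chromosomes. Without a filter on low bins the SD difference was -0.0122, since poorly mapped bins then enter both profiles.

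Centromeric regions, which are copied early in budding yeast, stood at 1.23 times the chromosome median in RWY012 and 1.21 times in RWY109. The median difference over 16 centromere windows, RWY109 minus RWY012, was 0.0057 log2 (-0.0032 to 0.017), with 9 of 16 windows positive, so that the median of the differences and the difference of the median levels had opposite signs. Random window lists of the same level had a median of 0.022, and the centromere list lay at percentile 1.82 among them. Among single windows, chosen after their values were seen, that around the centromere of chromosome VII was highest at 0.094 and that of chromosome XII lowest at -0.055. With windows reaching 40 kb to either side the percentile was 94.0, and under the other alternatives, windows of 15 kb included, it lay between 0 and 6.59.

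Chromosome ends, which are copied late, stood at 0.935 times the chromosome median in RWY012 and 0.895 times in RWY109. The median difference over 31 end windows was -0.025 log2 (-0.043 to -0.0022), with 14 of 31 windows positive, at percentile 6.53 of random lists. The lowest differences were -0.21 at the left end of chromosome I and -0.17 at the right end of chromosome III, and the highest was 0.093 at the left end of chromosome XII. With RWY012 thinned to the nuclear total of RWY109 the median difference was -0.010, at percentile 41.9. Over all alternatives the percentile ranged from 0, with end windows of 20 kb and a difference of -0.071, to 99.9, with end windows of 50 kb and a difference of 0.0089.

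Local differences between the profiles were then listed, a step added after the data were seen. The profile of RWY109 was set against a line through the RWY012 profile with a slope of 1.11. Departures from the line were averaged over 11 bins, and maxima in each direction were kept at least 20 bins apart on a chromosome. The 5 largest of these in each direction were taken. The lowest in RWY109 was on chromosome XI from 190001 to 191000, within OCT1, a mitochondrial peptidase gene. The level there was 0.975 times the chromosome median in RWY012 and 0.807 times in RWY109, a departure of -0.26 log2. This site lies in the stretch from 180001 to 203000 that is called as a copy number segment when the limit is lowered to 0.2 log2. Next were chromosome XV from 979001 near TYE7 at -0.25, chromosome IX from 138001 near RPI1 at -0.20, chromosome XV from 38001 near FRE7 at -0.20 and chromosome X from 159001 near LCB3 at -0.19. The highest in RWY109 was on chromosome V from 82001 to 83000, within RAD23, a nucleotide excision repair gene, at 1.04 times in RWY012 and 1.25 times in RWY109, a departure of 0.23. It was followed by chromosome III from 54001 within GID7 at 0.17, chromosome XII from 47001 near RNP1 at 0.16, chromosome VII from 123001 near YIP4 at 0.14 and chromosome IX from 402001 within DAL81 at 0.14. Between random subsets of RWY012 at the nuclear total of RWY109, the largest departure anywhere was 0.0776. Such subsets differ by counting error only, so that value does not cover technical differences between the 2 libraries. The regions were selected on these same counts, and no independent library was used to check them. Taken from odd or from even bins alone, 5 of them were over 1.5 times smaller in at least 1 of these sets, down to -0.098 at RPI1, -0.12 at FRE7, 0.060 at GID7, 0.074 at YIP4 and 0.087 at DAL81. Smoothing ran over a fixed number of bins, so in these sets it spanned more kb, which lowers narrow departures by construction. Every listed region was smaller in both sets, so the fall against all bins does not measure how well the regions repeat. The odd and even sets were smoothed alike, so that span does not account for differences between them. They differed most at GID7 (0.060 in odd and 0.12 in even bins), YIP4 (0.12 and 0.074) and RPI1 (-0.14 and -0.098). They were close at OCT1 (-0.23 and -0.22) and LCB3 (-0.17 and -0.17).

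**Figure D4:**
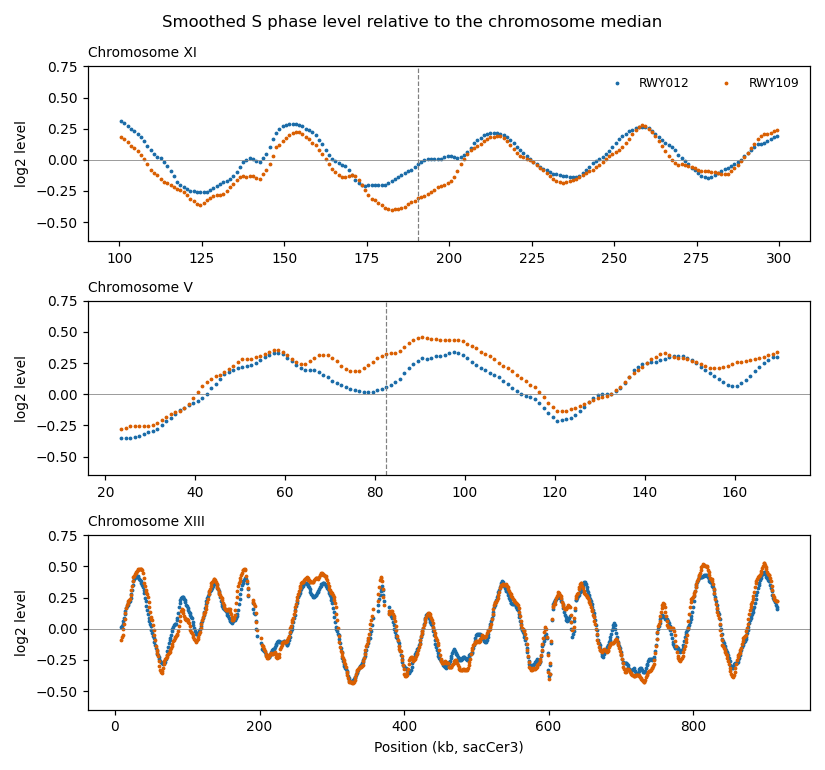
Smoothed log2 level relative to the chromosome median against position in kb for parts of chromosomes XI and V and for chromosome XIII, with dashed lines at regions listed among the 5 largest local departures in each direction. RWY109 lies below RWY012 around 190001 on chromosome XI and above it around 82001 on chromosome V, while chromosome XIII shows the shared pattern.

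Repeated and organelle DNA was counted relative to the nuclear median. The 2 bins of ribosomal DNA with more than 10 times the median, on chromosome XII from 459001 to 461000, stood at 82.9 times the median in RWY012 and 99.9 times in RWY109, a ratio of 1.20 (1.20 to 1.21). The bin from 459001 rose from 35.9 in RWY012 to 48.8 in RWY109, and that from 460001 from 130 to 151. Their changes differ by more than the pooled counting interval covers. These bins hold the RDN5-1 gene and an edge of RDN25-2, not the whole repeat. Relative to the level of chromosome XII in each library, the values were 58.7 and 101, a ratio of 1.72. Mitochondrial DNA stood at 15.04 times the median per kb in RWY012 and 10.9 times in RWY109, a ratio of 0.723 (0.722 to 0.725). It made up 9.70% of all counts in RWY012 and 7.26% in RWY109.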

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

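The alternatives were planned, except the profile difference without chromosomes IV, XI and XII, which was chosen after the data were seen, as was the 1.25-fold limit for genotype loci. No paired analysis was possible because each strain had 1 library. The 2 called chromosomes stayed called under all 9 alternatives, with chromosome XI between log2 0.56 and 0.57 and chromosome XII between 0.48 and 0.58. Another library scaling cannot move these ratios by construction. The chromosome IV segment was called under all 10, between log2 0.90 and 1.02, and without a filter it ran from 872001 to 988000. The low value came from the strict filter, which by construction removes bins above 200% of the chromosome median. At a segment difference of 0.2 there were 2 segments, the added one on chromosome XI from 180001 to 203000.

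The profile SD difference was 0.0234 with the strict filter, 0.0269 in odd bins, 0.0240 in even bins and 0.0265 without smoothing. Without a filter it reversed to -0.0122, as bins with few mapped reads dominate the SD by construction. The centromere difference reversed to -0.0016 in even bins and to -0.037 relative to bins 10 to 30 kb away, and was 0.020 in windows of 40 kb. The end difference was -0.010 after thinning, 0.0046 without a filter, -0.046 relative to bins 10 to 30 kb away, -0.071 in windows of 20 kb and 0.0089 in windows of 50 kb. The cause was not tested for the centromere and end lists. The direction of both is therefore open.

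The 4 genotype loci whose whole counting interval lay beyond 1.25-fold were RAD53, HIS3, TRP1 and LEU2. Bins wholly inside a gene gave 2, RAD53 and newly DBF4, since the other 3 loci hold no whole bin. Relative to bins 5 to 25 kb away there were 5, with DBF4 added at 0.748, while the interval of SLD3 (0.797, 0.761 to 0.835) crossed the limit. Scaled to nuclear totals, the ratio was 1.21 for the 2 pooled bins of ribosomal DNA and 0.729 for mitochondrial DNA. Not run were the GC correction and the 1 and 5 kb origin windows, which need a sequence and annotated origins.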

Other observations

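The tests of the loss of short chromosomes and of chance at the segment ends, the length trend and the matching of profile maxima were chosen after the results were seen. Profile maxima, sites where copy number peaks locally in S phase, were compared with RWY012 thinned to the nuclear total of RWY109. RWY012 had 218 maxima and RWY109 had 206, and 180 lay within 5 kb of a maximum in the other library. That is 82.6% of those in RWY012 and 87.4% of those in RWY109, against 90.2% between random subsets of RWY012. Those subsets differ by counting error only. Local departures above 0.1 log2 covered 7.82% of bins.

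Lower depth did not produce the wider profile of RWY109, since the SD difference was 0.0245 after the same thinning. Without chromosomes IV, XI and XII the SD difference was 0.0243, so the other chromosomes had the wider profile as well. This is no test of the gained DNA. Levels were relative to the median of each chromosome or segment, so a uniform gain could not enter the SD by construction. A different share of non-replicating cells in the sorted gate would scale the profile of every chromosome alike, with equal slopes of RWY109 on RWY012. Of 16 chromosomes, 0 had a slope below 1, but the wider profile of RWY109 nearly fixes that count, so it decides nothing. The slopes ranged from 1.02 on chromosome XIV (counting interval 1.00 to 1.05) to 1.19 on chromosome V (1.16 to 1.22). They thus differed by more than counting error, which 1 common share alone would not give. The spread between separate sorts of 1 strain is not known. With 1 sort per strain a part played by such a share cannot be told apart from a difference between the strains, which remains a hypothesis. A difference between the 2 libraries cannot be told apart either, as the GC correction was not run.

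Apart from chromosomes XI and XII, short chromosomes stood higher in RWY109 relative to RWY012, with r = -0.78 (permutation p = 0.00092) and rho = -0.77 (permutation p = 0.0022) against length over 14 chromosomes, and r = -0.74 without I and IV. Chromosomes of 2 libraries are not replicate samples, 4 such relations were computed, and the Benjamini-Hochberg value of the first is 0.0037. The wider profile and the distance to centromere and end each removed part of the excess, which on chromosome I fell from 0.064 log2 to 0.040 after a common line and to 0.024 after adjustment for distance. Over 14 chromosomes a trend stayed after each, which argues against either as the whole cause, with r = -0.73 after the line (adjusted permutation p = 0.0070) and r = -0.70 after the distance adjustment (adjusted permutation p = 0.0077), though the latter rests partly on I and IV (r = -0.56, permutation p = 0.059 without them). Loss of chromosomes I, III and VI in some RWY012 cells may contribute. Among the other 11 chromosomes r was -0.55 (permutation p = 0.075), or -0.21 without IV and IX. A ratio of the libraries cannot tell such a loss from a gain of these chromosomes in some RWY109 cells. Loss, gain and an untested difference between the strains are thus left open. So is a technical difference between the 2 libraries, as the GC correction was not run.

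Both ends of the chromosome IV segment lie in stretches without retained bins that hold Ty reading frames in the reference assembly. Of 10510 placements of a 97 kb interval on the genome, 9 had both ends in or within 1 kb of a stretch of at least 5 kb, or 0.0856%. There were 51 such stretches, and 30 of them held a reading frame over 4 kb with the suffixed kind of name that Ty frames carry. The length was taken from the called segment, so its own placement is 1 of the 9 by construction. Longer intervals, which the limits on the ends allow, were not tried. Chance placement is thus unlikely for an interval of 97 kb. Recombination between Ty copies is a candidate explanation, and no read across a junction was analysed here to test it.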
